A study of Mus musculus with 15 samples.

How the data were processed

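Gene expression was measured on 15 single-colour Agilent whole mouse genome oligonucleotide arrays (45018 features, of which 1639 were control spots). Per the labels' protocols, 10 ng of RNA from laser microdissected colon cells was carried through rounds of linear amplification, labelled with Cy3 and hybridised, 1 array per deposited sample. Per the file headers and the submitters' processing notes, the scans were read with Agilent Feature Extraction 9.5.3. The deposited scanner files hold, per spot, the mean and local background intensity and a processed intensity, which per the file headers was background-subtracted and spatially detrended within the array and not normalized between arrays. The deposited flags mark spots as well above background, saturated or outlying. The deposited value table of the authors holds log2 values; its sorted values differed by at most 0.0021 between columns, as after quantile normalization, and its background correction is not given in the sources used here. Of its columns, 11 matched their own scanner file best, while the 4 columns of the epithelium of tumor-bearing mice matched the files of that group in reverse order, so the table served only as an alternative, with each of these 4 columns set beside the file of its own group that it matched.

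Each spot's processed intensity was log2-transformed and the array's 75th percentile over non-control probes was subtracted, so levels are log2 values relative to that percentile. Control spots and spots flagged as outliers were left out, and spots of one probe were averaged. The 41174 non-control probes were named by RefSeq accession (22951), symbol (6650) or synonym (3097) from a RefSeq gene table of assembly GRCm38.p6, which was used for names only. The file's own name was kept for 2011 probes, and 6465 had no gene name. Probe coordinates are those of the array design, on mouse build mm7. Of several probes of a gene, the 1 with the highest mean over all arrays was used, giving 27765 features.

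Arrays of one group were compared before averaging. For each pair the SD of the log2 difference (from the median absolute deviation) was set against the spot noise that Feature Extraction reports as the coefficient of variation of replicate spots. Pairs of one group whose SD was below that noise were counted as 1 sample and averaged before the fit, which left 10 samples from 15 arrays. The design fixed before the data were examined treated all 15 arrays as samples, and that fit had been run and seen before the arrays were averaged; its counts are given as an alternative.

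Differences were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on all 4 groups together, with 6 residual and 3.9 prior degrees of freedom, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A feature was tested where it was well above background on every array of at least 1 of both groups compared, with at least 2 unflagged arrays. A gene not well above background on any array of a group has only a bound there. Its fold is given as "at least". On each array of that group the higher of the lowest well-above-background signal and its own signal was taken. These values were averaged within each sample and then over samples, and the fold was computed against that mean. The 16 pathway lists and 16 cell type lists, fixed before the data were examined, were tested with the camera form of limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Adjusted p-values of lists are over the lists of a comparison.

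Named genes followed a rule fixed before the data were examined. It took the genes with the highest rise and fall among called genes measured in both groups without overlap, and the called genes with the highest bounds. It also took the members with the highest moderated t of each list that passed and of 4 lists always, plus a fixed set of cholesterol, prostaglandin, Wnt and cell cycle genes. Where fewer than 4 genes passed in a direction, those with the highest moderated t were named as not past the threshold. Predicted genes and clone names were left out.

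On simulated arrays with the measured means and spread and the same shared samples, in which 200 genes were changed by 4 on the log2 scale, limma recovered 70% of them in the design of the treated against the untreated adenomas (17636 genes tested). For a change of 2 it recovered 0% there, and for a change of 6 it recovered 91.5%. In the design of the 2 epithelia (17657 genes tested) the shares at 2, 4 and 6 were 0%, 81% and 96%. The list test found a list shifted by -2 in 10 of 10 draws and called no other list in any of them. Simulated genes varied independently of each other. In the adenoma comparison the estimated inter-gene correlation was 0.2 for goblet and 0.33 for mast cell markers. The draws therefore cannot show how often lists of correlated genes are called falsely.

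Alternatives covered the background correction (normexp with an offset of 50), quantile and median scaling, filters, separate probes, the authors' table, slide and scan date as blocks, the replicate number as a block, array weights, fits of only both groups compared, and leaving out each array. Alternatives chosen after seeing the data were each array as its own sample, the shared RNA as a random block, leaving out whole samples, leaving out a near-identical pair of epithelium arrays, keeping the outlier spots, and leaving out both arrays with many such spots. The labels call the arrays biological replicates without tying each to a mouse, so p-values measure the spread between these samples, which may be technical in part. The number of arrays limits the precision. Some genes and a list are not reported here. Untreated epithelium is not analysed here.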

Results

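The samples came from male Apc+/Min-FCCC mice, which carry a mutant copy of the tumor suppressor Apc and develop colorectal adenomas. Colonoscopy at 6 to 8 weeks of age sorted the mice into tumor-bearing and tumor-free animals. The drugs were given in chow for 7 days. Sulindac, a nonsteroidal anti-inflammatory drug that blocks cyclooxygenases, was given at 300 ppm, and atorvastatin, a cholesterol-lowering statin, at 100 ppm. Microdissected adenoma cells came from untreated mice (3 arrays) and from mice given both drugs (4 arrays). Microdissected normal colon epithelium came from atorvastatin-treated tumor-free mice (4 arrays) and from atorvastatin-treated tumor-bearing mice (4 arrays). The protocol text assigns tumor-bearing mice to untreated chow or to both drugs, while the labels of the latter 4 arrays name atorvastatin alone; the labels were followed. Between 56.5% and 75.5% of probes were well above background on an array. Outlier flags covered 9.12% of spots on untreated adenoma array 2 and 7.81% on array 1 of the tumor-bearing epithelium, and at most 1.14% on the others. The arrays lay on 11 slides scanned on 6 dates.

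Several arrays of one group were near-identical. Untreated adenoma arrays 1 and 2, treated adenoma arrays 2, 3 and 4, tumor-free epithelium arrays 3 and 4, and tumor-bearing epithelium arrays 1 and 3 made 6 pairs. They differed by an SD of 0.09 to 0.17 on the log2 scale, below the spot noise of 0.19 to 0.22, with Pearson's r across probes of 0.994 to 0.998. The 15 other pairs within a group differed by 0.59 to 1.12. The near-identical arrays differed by less than the spot noise, the measure of sampling noise used here, and were counted as 1 sample, which left 2 untreated adenoma, 2 treated adenoma, 3 tumor-free and 3 tumor-bearing epithelium samples. A pair across groups was also near-identical: array 2 of the tumor-free and array 2 of the tumor-bearing epithelium differed by 0.18, with a spot noise of 0.18 and an r of 0.994. Both were kept under their labels, and every comparison that uses tumor-bearing epithelium carries this doubt. The spread was estimated from all 4 groups together, and the epithelium groups hold more samples than the adenoma groups. The p-values between the adenomas therefore rest largely on the spread of the epithelium, including this pair.

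**Figure D1:**
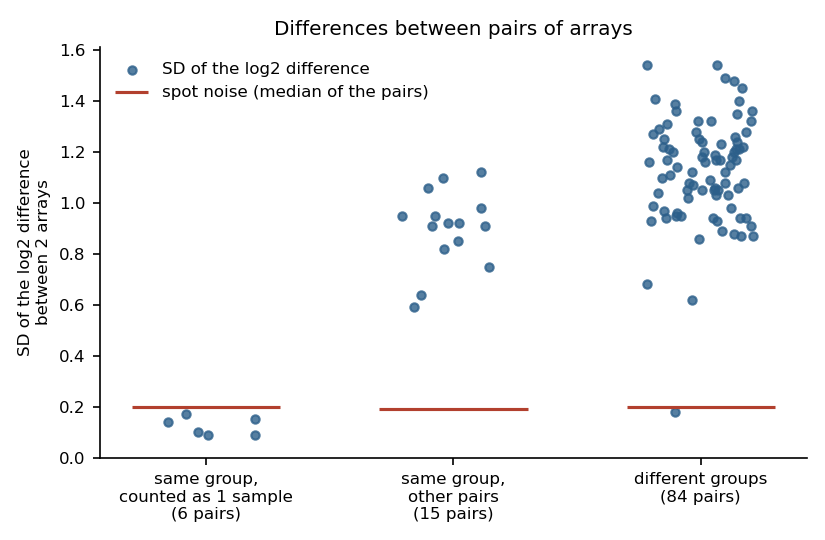
Standard deviation of the log2 difference between the arrays of each pair (y axis, log2 units), for pairs counted as 1 sample, other pairs of a group and pairs across groups; red lines show the median spot noise. The 6 pairs counted as 1 sample lie at 0.09 to 0.17, the 15 other pairs within a group at 0.59 or above, and 1 pair across groups at 0.18.

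The first comparison asked how a week of sulindac with atorvastatin altered gene expression in adenomas; both drugs were given together, so their effects cannot be told apart. In the treated adenomas Mptx1, a mucosal pentraxin of the colon, was at least 495-fold higher than in untreated adenomas (adjusted p = 0.000126, limma). Its probe (chromosome 1, 174299277 to 174299336, mm7) was well above background on 4 of 4 treated and 0 of 3 untreated arrays. Zg16, a lectin secreted by goblet cells, fell 85.6-fold (log2 difference -6.42 ± 0.99 SE, adjusted p = 0.0397), and Mcpt2, a protease of mucosal mast cells, was at least 7.4-fold lower (adjusted p = 0.011). Nqo1, a quinone reductase of xenobiotic defence, fell 6.76-fold (log2 difference -2.76 ± 0.45 SE, adjusted p = 0.0499). In all, 40 of 17636 genes were called, 22 higher and 18 lower in treated adenomas, and 2105 had an unadjusted p under 0.05.

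Among genes measured in both groups, the highest rises were those of the metallothionein Mt4 (25.1-fold, adjusted p = 0.0296), the muscle protein gene Smpx (17.5-fold), the alpha-defensin Defa29 (17.2-fold) and the thyroid hormone-binding protein gene Crym (13.1-fold). Pdzrn4 and the neuropeptide Y receptor gene Npy2r were at least 8.79-fold and 8.52-fold higher. The deepest falls after Zg16 were those of the immunoglobulin heavy chain segment Igh-VJ558 (41.9-fold), F13a1, which encodes the A chain of coagulation factor XIII (23.4-fold), the membrane mucin Muc3 (23.3-fold, adjusted p = 0.0296) and the lens crystallin Crybb1 (15.8-fold). Rnase2b, an eosinophil-type ribonuclease, was at least 69.9-fold lower, and Hao2, a peroxisomal hydroxyacid oxidase, at least 6.15-fold lower (adjusted p = 0.011). Probes for alpha-defensins and immunoglobulin segments can bind related family members.

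Of the 32 lists, 5 passed the camera test, all lower in treated adenomas, and none of them passed with an estimated correlation. Goblet cell markers had a median log2 difference of -1.92 (adjusted p = 1.4e-07, and adjusted p = 0.496 with an estimated correlation). Of 13 members tested 1 fell, and 8 fell when adjusted over the list alone; Muc2, the main secreted mucin, lay at -0.28 ± 2.68 in treated against 5.12 ± 1.29 in untreated adenomas (SD, n = 2 and 2, limma adjusted p = 0.105). The median of the mast cell markers was -3.39 (adjusted p = 0.00013, and adjusted p = 0.545 with an estimated correlation), with 1 of 7 members called and 5 when adjusted over the list alone. Absorptive colonocyte markers had a median of -1.3 and no member called (adjusted p = 0.00277, and adjusted p = 0.601 with an estimated correlation). For the cell cycle list the median was -0.41 with 0 of 34 members called (adjusted p = 0.00065, and adjusted p = 0.839 with an estimated correlation). For xenobiotic metabolism it was -0.3 with 1 of 22 called, 3 when adjusted over the list alone (adjusted p = 0.0463, and adjusted p = 0.545 with an estimated correlation).

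Neither Ptgs2, which encodes cyclooxygenase-2, nor the Wnt targets named here were called. Ptgs2 differed by -1.29 ± 1.29 (SE, adjusted p = 0.752). Among Wnt targets, Myc differed by -1.46 ± 0.45 (adjusted p = 0.269), Axin2 by 0.93 ± 0.51 (adjusted p = 0.518) and the stem cell receptor gene Lgr5 by 0.35 ± 0.58 (adjusted p = 0.86). The lists of cholesterol synthesis and uptake, of Wnt targets and of the prostaglandin pathway had adjusted p of 0.717, 0.763 and 0.268; the cholesterol median was 0.17, while its mean of -0.1 and its test pointed down. Enteroendocrine markers, another epithelial type, had a median of 0.23 (adjusted p = 0.771).

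Scan dates 2 and 5 held both adenoma groups. Within them Zg16 differed by -9.04 and -3.53, so its fold varied with the samples compared. The goblet medians were -2 and -1.83, the mast cell medians -3 and -2.81 and the xenobiotic medians -1.17 and -0.26. The absorptive medians of -2.32 and -0.03 and the cell cycle medians of -0.01 and -0.6 lay near 0 on 1 date each. With scan date as a fixed block on separate arrays, fitted without the tumor-free epithelium, 2084 genes and 6 lists were called. With each of the 15 arrays as its own sample 2329 genes were called. Both fits counted near-identical arrays as separate samples, which narrows the measured spread, so their higher counts are no separate support. The same holds for every fit on separate arrays given below, except that with the RNA as a random block. Leaving out treated array 1, which alone made up 1 of that group's 2 samples, left 1 gene called; leaving out untreated array 3 left 11, and untreated arrays 1 and 2 left 5 genes and 3 lists.

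**Figure D2:**
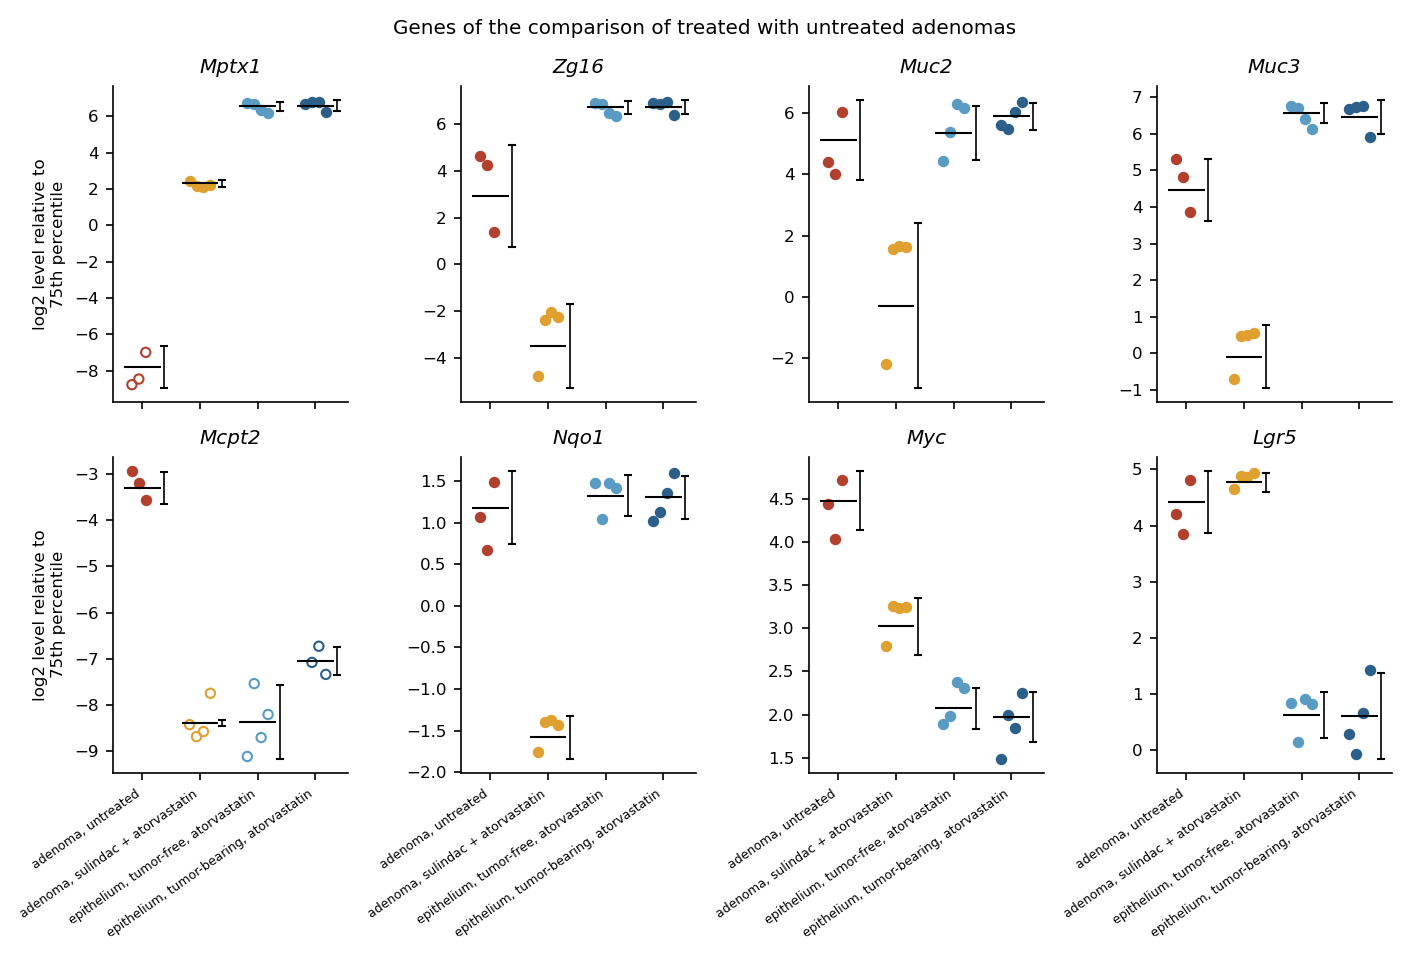
Log2 level relative to the array's 75th percentile (y axis) of 8 genes on each array of the 4 groups (x axis); filled points were well above background and open points were not, horizontal lines show the mean over samples and bars the SD over samples. Zg16 lay at -3.51 in treated and 2.91 in untreated adenomas.

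The second comparison set the epithelium of tumor-bearing against that of tumor-free mice, both given atorvastatin. No gene was called by limma (0 of 17657), and 447 genes had an unadjusted p under 0.05. Treating each array as its own sample gave 2 genes, and the shared RNA as a random block gave 1. The genes with the highest moderated t, none past the threshold (adjusted p = 0.996 for each), were D2hgdh, a mitochondrial dehydrogenase gene (10.5-fold), Serpinf2, which encodes alpha-2-antiplasmin (9.56-fold), Pitpnm2 (8.29-fold) and the parathyroid hormone-like gene Pthlh (4.67-fold), with higher values in tumor-bearing mice. Lower values were measured for Slfn3 (12.2-fold), Jrkl (6.93-fold), Prdm8 (at least 2.83-fold) and Gpr85 (at least 1.34-fold). Hmgcs1 and Sqle, genes of cholesterol synthesis, differed by -0.1 and -0.24 (adjusted p = 0.996 for each).

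Of the lists, 5 passed the camera test at the preset correlation, with 0 members called in each. MHC class II presentation genes had a median log2 difference of 0.75 (adjusted p = 0.0284), goblet cell markers 0.3 (adjusted p = 0.0382), red blood cell markers 1.43 (adjusted p = 0.0382) and macrophage and dendritic cell markers 0.35 (adjusted p = 0.0435), all higher in tumor-bearing mice. Cell junction genes had a median of -0.5 (adjusted p = 0.0284). For each of the 5 lists, adjusted p = 0.858 with an estimated correlation. The class II transactivator Ciita differed by 1.69 ± 0.72 (SE), the complement gene C1qa by 2.25 ± 1.24, the tight junction gene Tjp1 by -1.71 ± 0.63 and the goblet transcription factor gene Spdef by 1.74 ± 0.73. The list calls numbered 1 under quantile normalization, with the authors' table and with array weights, and 0 with the RNA as a random block. They numbered 8 without tumor-free array 1, 3 without tumor-free array 4, 1 without tumor-bearing array 4, 1 without tumor-free arrays 3 and 4, and 3 without tumor-bearing arrays 1 and 3. No scan date held both epithelium groups, and the near-identical pair across groups belongs to this comparison; without both arrays 0 genes were called. With array weights, tumor-bearing array 4 had the lowest weight, 0.31, against 0.82 to 1.88 for the other samples.

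The third comparison set untreated adenoma against the epithelium of tumor-bearing mice, so tissue and atorvastatin cannot be told apart. Wnt target genes were higher in adenoma, as were neutrophil markers, while genes of xenobiotic metabolism and markers of enteroendocrine cells were lower. Mmp7, a matrix protease and Wnt target, rose 922-fold (log2 difference 9.85 ± 1 SE, adjusted p = 0.000386) and Spp1, which encodes osteopontin, was at least 1230-fold higher (adjusted p = 1.5e-05). Mptx1 was at least 9560-fold lower (adjusted p = 1.67e-06) and Insl5, a hormone of colonic enteroendocrine cells, fell 527-fold (adjusted p = 1.46e-05). Of 17409 genes, 867 were higher and 1161 lower in adenoma.

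Of 24 Wnt targets 17 rose (median log2 difference 3.39, adjusted p = 1.04e-16, and adjusted p = 0.0268 with an estimated correlation). Axin2 rose 8.16-fold, Lgr5 14.1-fold and Myc 5.68-fold, and the Wnt inhibitors Dkk2 and Notum were at least 409-fold and 166-fold higher. Neutrophil markers rose for 7 of 10 members (camera adjusted p of the list = 1.32e-08, and adjusted p = 0.0388 with an estimated correlation), S100a8 by at least 135-fold. Inflammatory cytokine and acute response genes rose for 13 of 24 (adjusted p = 2.52e-09, and adjusted p = 0.0838 with an estimated correlation), among them Il1b by 83.2-fold; Il1rl1, the receptor of interleukin-33, rose 203-fold. Ptgs2 rose 78.8-fold (adjusted p = 0.0086) and Hpgd, which degrades prostaglandins, fell 11.7-fold (adjusted p = 0.00534). The Paneth and deep crypt list rose for 5 of 8 members (adjusted p = 1.28e-05, and adjusted p = 0.0838 with an estimated correlation), with the alpha-defensin Defa1 at least 517-fold higher; Defcr6, an alpha-defensin outside the list, was at least 617-fold higher. Mast cell markers rose for 5 of 8 members (adjusted p = 0.000465, and adjusted p = 0.173 with an estimated correlation), stem cell markers for 5 of 13 with 1 lower (adjusted p = 0.000465, and adjusted p = 0.0838 with an estimated correlation). The stem cell list shares Lgr5, Ascl2, Axin2, Rnf43, Tnfrsf19 and Sox9 with the Wnt list, and the Paneth list shares Mmp7 with it. Rises of these lists, here and in the fourth comparison, are therefore not separate from that of the Wnt targets. Cell cycle genes rose for 3 of 34 (adjusted p = 1.17e-05, and adjusted p = 0.311 with an estimated correlation), Rrm2 by 4.68-fold, while the proliferation marker Mki67 differed by -0.38 ± 0.49 (adjusted p = 0.632). Krt17, a keratin, rose 165-fold and Fam89a 116-fold.

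Xenobiotic metabolism genes fell for 13 of 24 members with 1 higher (adjusted p = 7.69e-07, and adjusted p = 0.0268 with an estimated correlation); the sulfotransferase Sult1a1 fell 325-fold and Cyp2c55, a cytochrome P450, 261-fold. Enteroendocrine markers fell for 9 of 14 with 1 higher (adjusted p = 3.6e-06, and adjusted p = 0.0268 with an estimated correlation), and Gcg, the proglucagon gene, was at least 979-fold lower. Absorptive colonocyte markers fell for 8 of 17 (adjusted p = 3.6e-06, and adjusted p = 0.0978 with an estimated correlation), Slc26a3, a chloride transporter, by 379-fold. Goblet cell markers fell for 5 of 13 (adjusted p = 0.00281, and adjusted p = 0.291 with an estimated correlation), Clca1 by 28-fold. Sult1c2 fell 437-fold, Hao2 255-fold, and Cyp2f2 was at least 504-fold lower. Fatty acid oxidation and PPAR target genes fell for 5 of 24 with 1 higher (adjusted p = 0.0198, and adjusted p = 0.308 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.62 and 1 member called (adjusted p = 0.00281, and adjusted p = 0.594 with an estimated correlation), and MHC class II genes -1.57 and no member called (adjusted p = 0.0371, and adjusted p = 0.623 with an estimated correlation).

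Of the other cell types, B and plasma cell markers fell for 5 of 9 members (camera adjusted p of the list = 4.44e-06, and adjusted p = 0.122 with an estimated correlation), the joining chain gene Jchain by 129-fold. Smooth muscle markers fell for 6 of 12 (camera adjusted p of the list = 0.00355, and adjusted p = 0.291 with an estimated correlation), Cnn1 by 20.4-fold. Red blood cell markers fell for 2 of 4 (camera adjusted p of the list = 0.0198, and adjusted p = 0.311 with an estimated correlation). Fibroblast and endothelial markers had medians of -0.12 and 0.4 (adjusted p = 0.772 and 0.191); the fibroblast mean was 0.14, opposite in sign to its median.

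Within scan dates 1 and 2, which held both groups, the Wnt medians were 3.7 and 3.36 and the xenobiotic medians -2.47 and -2.74. The enteroendocrine medians were -3.56 and -4.99, and 100% and 99.9% of called genes kept their direction. Untreated arrays 1 and 2 were counted as 1 sample, as were tumor-bearing arrays 1 and 3, so both dates measured largely the same samples. The genes were also called from these arrays, so the agreement between dates is no separate support. Counts ranged from 586 without untreated array 3 to 3702 without tumor-bearing array 4; they were 887 without untreated arrays 1 and 2, 1235 without tumor-bearing arrays 1 and 3, 1190 without the near-identical pair, and 6059, with 18 lists, with scan date as a fixed block on separate arrays.

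**Figure D3:**
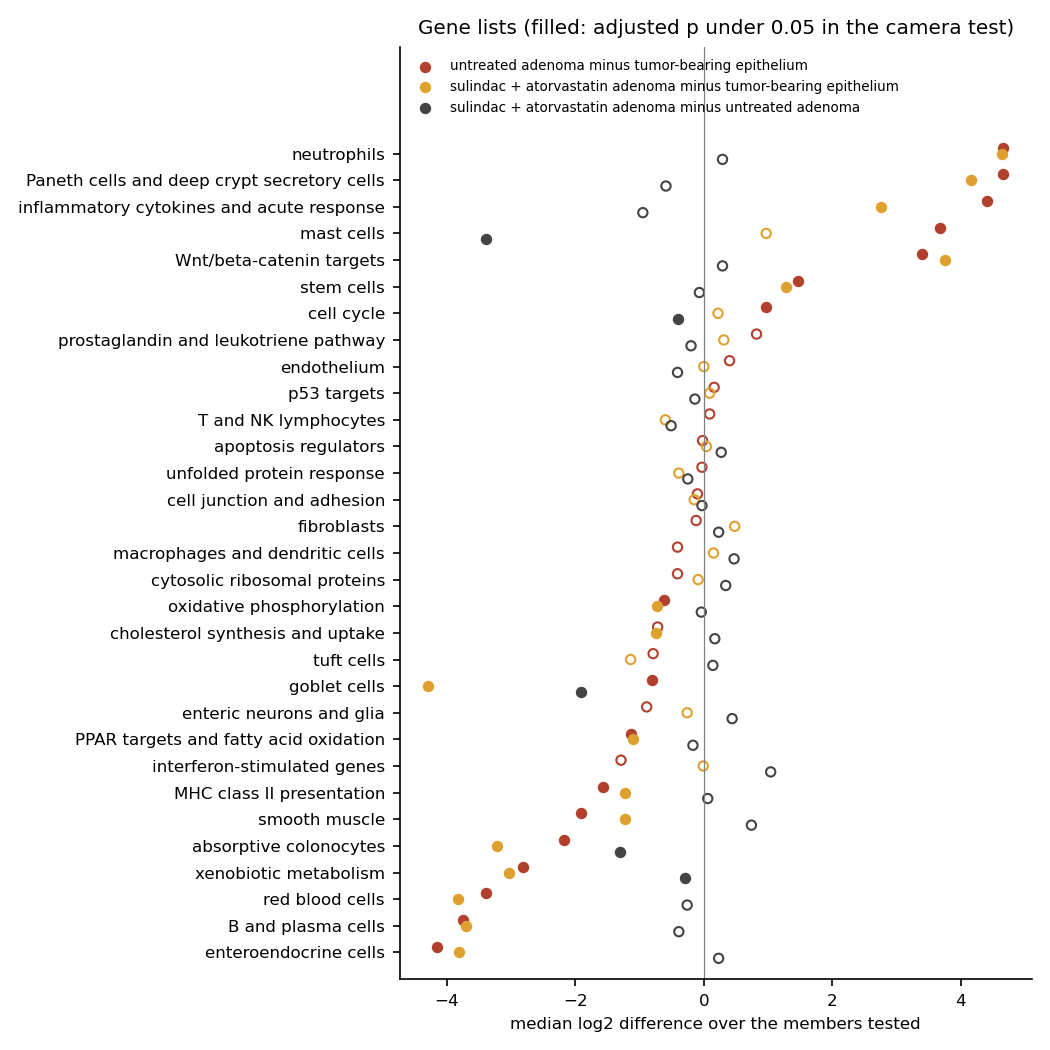
Median log2 difference over the tested members of each list shown (x axis) for 3 comparisons (colours); filled points have an adjusted p under 0.05 in the camera test. Wnt targets lie at 3.39 and 3.76 in the comparisons of adenoma with epithelium, and goblet cell markers at -0.81 and -4.29.

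The fourth comparison set treated adenoma against the same epithelium, both given atorvastatin, so tissue and sulindac cannot be told apart. The epithelium samples are those of the comparison before, so shared chance values enter both. Wnt targets were higher in treated adenoma and xenobiotic and enteroendocrine genes lower. Mmp7 rose 673-fold (log2 difference 9.39 ± 1 SE, adjusted p = 0.000367) and Spp1 was at least 1820-fold higher (adjusted p = 9.38e-06). Aqp8, a water channel of colonocytes, fell 1500-fold (adjusted p = 0.000639) and Zg16 1210-fold (adjusted p = 0.000127). Of 17010 genes, 1120 were higher and 1105 lower in treated adenoma.

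Wnt targets rose for 16 of 24 members (median 3.76, adjusted p = 3.92e-13, and adjusted p = 0.0447 with an estimated correlation): the inhibitors Nkd1, Dkk2 and Notum rose 194-fold, at least 615-fold and at least 446-fold, Lgr5 18-fold and Axin2 15.5-fold, whereas Myc differed by 1.05 ± 0.41 (adjusted p = 0.122). Neutrophil markers rose for 7 of 10 (adjusted p = 1.22e-07, and adjusted p = 0.0557 with an estimated correlation) and inflammatory genes for 14 of 25 (adjusted p = 4.2e-06, and adjusted p = 0.143 with an estimated correlation), with Il1b 79.6-fold higher. Paneth markers rose for 5 of 8 with 1 lower (adjusted p = 0.00185, and adjusted p = 0.174 with an estimated correlation), Defa1 by at least 621-fold, and stem cell markers for 5 of 13 with 1 lower (adjusted p = 0.00279, and adjusted p = 0.127 with an estimated correlation). Defcr6, outside these lists, was at least 643-fold higher. Ptgs2 rose 32.3-fold (adjusted p = 0.0213) and Hpgd fell 11.2-fold (adjusted p = 0.00492). The proteoglycan gene Spock2 rose 158-fold, the lipoxygenase Alox12 148-fold and the lipase-related gene Pnliprp1 136-fold.

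Xenobiotic genes fell for 17 of 23 members with 1 higher (adjusted p = 6.07e-11, and adjusted p = 0.0236 with an estimated correlation), enteroendocrine markers for 9 of 14 with 1 higher (adjusted p = 3.22e-06, and adjusted p = 0.03 with an estimated correlation). Absorptive markers fell for 11 of 17 (adjusted p = 7.22e-09, and adjusted p = 0.0639 with an estimated correlation) and goblet markers for 8 of 13 (adjusted p = 1.6e-08, and adjusted p = 0.0756 with an estimated correlation). Fabp2, an intestinal fatty acid-binding protein gene, fell 472-fold, the syncollin gene Sycn 463-fold and Insl5 408-fold. Hao2, the carbonic anhydrase gene Car4 and the gasdermin gene Gsdmc2 were at least 1570-fold, 1070-fold and 448-fold lower. Cholesterol synthesis and uptake genes had a median of -0.74 (camera adjusted p of the list = 0.0154, and adjusted p = 0.436 with an estimated correlation). Of 25 members 1 was called, Mvk, mevalonate kinase, 3.59-fold lower. In untreated adenoma against the same epithelium the list median was -0.72, also with 1 member called (camera adjusted p of the list = 0.0682). Fatty acid oxidation and PPAR target genes fell for 4 of 22 (adjusted p = 0.0059, and adjusted p = 0.286 with an estimated correlation), oxidative phosphorylation genes for 1 of 30 (adjusted p = 0.000264, and adjusted p = 0.529 with an estimated correlation), and MHC class II genes had a median of -1.23 with no member called (adjusted p = 0.0416, and adjusted p = 0.748 with an estimated correlation).

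B and plasma cell markers fell for 6 of 8 (adjusted p = 9.79e-07, and adjusted p = 0.127 with an estimated correlation), smooth muscle markers for 2 of 11 (adjusted p = 0.00826, and adjusted p = 0.286 with an estimated correlation) and red blood cell markers for 3 of 4 (adjusted p = 0.00826, and adjusted p = 0.286 with an estimated correlation). The mast cell median was 0.97 (adjusted p = 0.279). Within scan dates 2 and 4 the Wnt medians were 4.46 and 3.78 and the xenobiotic medians -4.29 and -2.39. The goblet medians were -4.77 and -4.25 and the enteroendocrine medians -4.22 and -3.84, whereas the MHC class II medians of -3.28 and 0.26 went opposite ways. Smaller on date 4 were the medians of fatty acid oxidation and PPAR targets (-1.63 and -0.18), oxidative phosphorylation (-0.97 and -0.28) and cholesterol genes (-1.04 and -0.32). Counts ranged from 858 without treated array 1 to 3564 without tumor-bearing array 4; they were 1120 without treated arrays 2, 3 and 4, 1499 without the near-identical pair, and 4838, with 16 lists, with scan date as a fixed block on separate arrays.

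**Figure D4:**
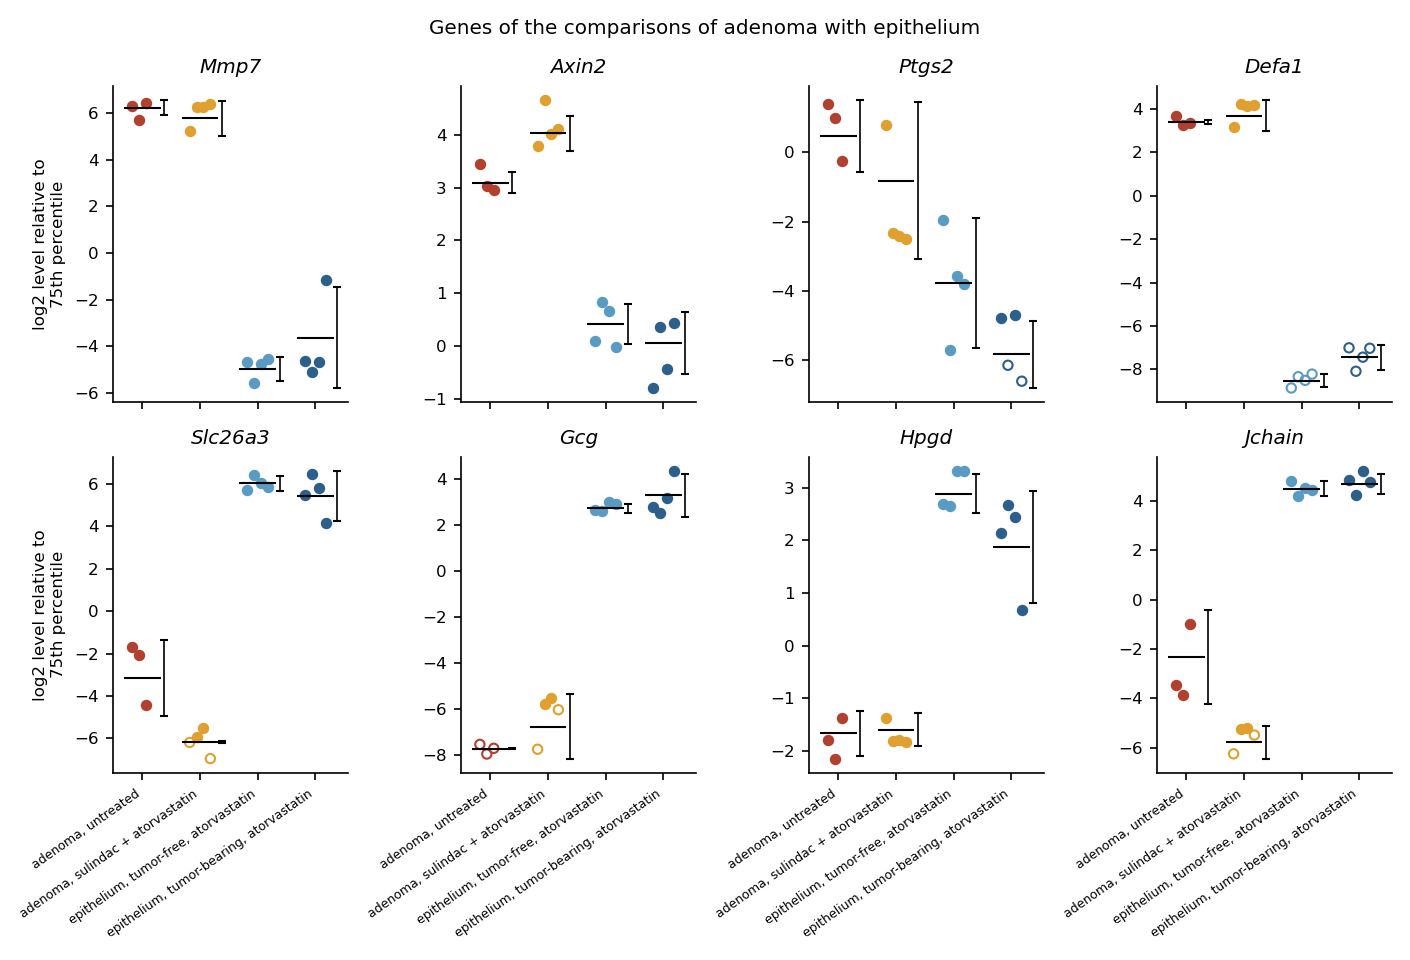
Log2 level relative to the array's 75th percentile (y axis) of 8 genes on each array of the 4 groups (x axis); filled points were well above background and open points were not, horizontal lines show the mean over samples and bars the SD over samples. Axin2 lay at 3.09 and 4.02 in the adenoma groups and at 0.07 in tumor-bearing epithelium, and Hpgd at -1.67, -1.6 and 1.88.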

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

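Chosen after seeing the data were the separate arrays, the RNA as a random block, the samples and the near-identical pair left out, and the outlier spots. No list or named gene called in the report or in an alternative changed direction between them; values within single scan dates, some of which did, are given in the report. Of the values for lists, 768 of 800, 723 of 798, 798 of 830 and 840 of 862 kept their side of the threshold in the order of the report. Of those for named genes 1033 of 1236, 1161 of 1163, 1427 of 1522 and 1443 of 1522 did. Most lists were not called between the adenomas or between the epithelia, and such lists have no call to lose. List calls were lost in 15, 50, 12 and 15 of the values and gained in 17, 25, 20 and 7. The list tests with an estimated correlation and with fry are not among these values. Their counts follow in the next paragraph, and the estimated correlation removed most list calls. Calls of named genes were lost in 102, 0, 51 and 22 and gained in 101, 2, 44 and 57. Fewer genes or samples entered under some alternatives. The fits with separate arrays, and those with slide, scan date or replicate number as a block, counted near-identical arrays as separate samples. Their higher counts thus come with repeated arrays counted as replicates, and do not show the effect of the block alone. With the RNA as a random block, the arrays of a block correlated at 0.888. For the other alternatives the cause was not tested. For treated against untreated adenoma (40 genes) the count was 2329 with each array its own sample, 2205 with slide and 3009 with scan date as a random block, 2084 with scan date as a fixed block, 99 with the RNA as a random block, 103 with only both groups fitted, 26 without a filter on dim probes and 1 with probes well above background in both groups. For untreated adenoma against epithelium (2028) the count was 6518 with separate arrays, 6793 with slide, 7343 and 6059 with scan date, 1312 with only both groups, 1140 with probes well above background in both, 4095 with array weights and 1190 without the near-identical pair. For treated adenoma against epithelium (2225) the counts in the same order were 6765, 6268, 6944, 4838, 1388, 1141 and 3507 (array weights). Between the epithelia, 0 genes became 2 with separate arrays and 1 with the RNA block (447 at an unadjusted p under 0.05, limma).

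With the replicate number as a block on separate arrays the counts were 2416, 6853 and 6741. Without it the counts for separate arrays were 2329, 6518 and 6765. Arrays of different groups that share a number correlated at -0.19 to 0.46 in their deviations from the group means. Those with different numbers correlated at -0.45 to 0.34. The highest values, 0.46 and 0.42, shared a number. The 0.46 is that of treated adenoma array 1 with tumor-free epithelium array 1, and 0.42 is that of the near-identical epithelium pair. By their labels the groups differ in treatment or in tumors and share no mouse, so as labelled the numbers cannot pair arrays of one mouse. Whether they pair samples in another way stays open. Leaving out each array or sample gave 1 to 40, 0 to 0, 586 to 3702 and 858 to 3564 genes, and 3 to 7, 1 to 8, 15 to 19 and 15 to 17 lists; a group left with 1 sample was assumed to vary like the others. The lists called (5, 5, 17 and 16) became 0, 0, 4 and 3 with an estimated correlation, and 0, 0, 18 and 16 with fry. Between the adenomas 3 lists passed with probes well above background in both groups; between the epithelia 1 passed with quantile normalization, the authors' table and array weights, and 0 with the RNA block. The authors' table moved the median of all genes by -0.111 between the adenomas and by 0.127 between untreated adenoma and epithelium. Scan date as a fixed block could not be fitted between the epithelia, and lists were not run with every probe separate. Signal near background limits genes whose folds are given as bounds.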

Other observations

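The tests of near-identical arrays, scan dates, connective tissue markers and single deep genes were chosen after the values were seen.

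Other lists did not pass between treated and untreated adenomas. Interferon-stimulated genes had a median log2 difference of 1.04 (adjusted p = 0.31), with medians of 0.47 and 1.32 within scan dates 2 and 5. Inflammatory cytokine and acute response genes had a median of -0.95 (adjusted p = 0.0863), with -1.35 and -0.19 within those dates. Cytosolic ribosomal protein genes had a median of 0.34 (adjusted p = 0.763). The unfolded protein response and T and NK lymphocyte lists had medians of -0.25 and -0.51 (adjusted p = 0.178 and 0.203). The p53 target and tuft cell lists, whose medians of -0.14 and 0.14 were opposite in sign to their means of 0.06 and -0.04, had an adjusted p of 0.763 each.

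A candidate explanation for the near-identical arrays is that one RNA was hybridised more than once. Against a shared slide or scan date as the cause, 5 of the 6 pairs lay on different slides and 4 on different dates, while other arrays that share a date differed by at least 0.59. Separate animals with alike RNA are argued against by the gap within groups: the closest other pair within a group differed 3.5 times as much as the farthest near-identical pair. The pair across groups was left out of this gap, and its labels name separate animals. The argument therefore holds only if a label of that pair is wrong. For the pair under both epithelium labels the SD of 0.18 lies with the near-identical pairs, so the same RNA under both labels may be the cause, and which label is right stays open. No biological explanation was tested for this pattern.

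Goblet and mast cell markers passed as lower in treated adenomas only at the preset correlation (adjusted p = 0.496 and adjusted p = 0.545 with an estimated correlation), so any effect of the drugs on these cells stays open. Scan date is argued against as the source of the lower medians, since the within-date median nearest to 0 was -1.83. For normal epithelium mixed into the untreated samples, the test set before its value was seen went with it, since only 1.1% of abundant epithelium genes lay below the 7.06% share that Zg16 would need, but many of these genes are made by adenomas too (their median difference was -0.57), which weakens this test. A second test, added after that value was seen, argues against it as the whole cause: 26 abundant epithelium genes lay over 2 on the log2 scale below that share, 22 of them well above background on every unflagged untreated array, such as Insl5 at -9.04 and Slc26a3 at -8.57 against -3.82 for Zg16. Mast cell markers were higher in untreated adenoma than in tumor-bearing epithelium (median 3.67, 5 of 8 members called higher and 0 lower). This argues against mixed-in epithelium as the source of the mast cell pattern. That list did not pass the camera test with an estimated correlation (adjusted p = 0.173). For the goblet markers, goblet cells mixed in alone stay open. Both tests and the mast cell comparison took epithelium labelled as atorvastatin-treated as the reference, including the array of the near-identical pair. Epithelium mixed into the untreated samples would be untreated, and that tissue is not analysed here. These arguments therefore hold only as far as the drug left the genes used unchanged.

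Smooth muscle, B and plasma and red cell markers passed as higher in epithelium than in adenoma at the preset correlation and with fry, though not with an estimated correlation, and for this tissue captured below the epithelium is a candidate source. Fibroblast and endothelial medians lay at least 1.23 above the smooth muscle median in both comparisons, but members of a list differed by an SD of up to 1.7 and the adenomas' own stroma can offset these markers. Captured tissue therefore stays open, as do muscle, blood or plasma cells taken alone and the tissues themselves.

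Regrouping the samples gave too few splits for a share under 0.05. In the treated against untreated adenomas 1 of 3 splits reached the real count of 40, the highest other count being 0. Between adenoma and epithelium 1 of 10 splits reached 2028 (highest other 948) and 1 of 10 reached 2225 (highest other 716). Between the epithelia all 10 splits reached the real 0, and others called 5, 7 and 79 genes. The split with 79 set both near-identical arrays on the same side, which points to a structure of the samples that the labels do not give. The splits with 5 and 7 did so too, but so did 1 with 0, so whether this pair is that structure stays open. More than this pair crossed the labels. Tumor-bearing array 4 differed by 0.93 and 0.88 from tumor-free arrays 3 and 4, but by 1.06 to 1.12 from its own group. Tumor-free array 2 differed by 0.68 and 0.62 from tumor-bearing arrays 1 and 3, but by 0.85 to 0.92 from its own group. The split with 79 set each of them with those nearer arrays. An adenoma array crossed the labels too. Treated adenoma array 1, which alone makes up 1 of that group's 2 samples, differed by 0.94 from tumor-free epithelium array 1. It differed by 0.92 to 0.98 from its own group and by 1.32 to 1.45 from the other tumor-free arrays. The cause was not tested, and the comparisons that use treated adenoma carry this doubt.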
